A study of Bacillus thuringiensis with 4 samples.

How the data were processed

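RNA from 4 time points of a culture of Bacillus thuringiensis CT-43 was sequenced by the authors. Per the labels' protocols, cells were grown with shaking at 28 °C, RNA was extracted with TRIzol and treated with DNase, and ribosomal and transfer RNA were depleted with an exonuclease that digests RNA with a phosphate at its front end. Double-stranded cDNA was then made with an RNA-Seq library kit. Per the labels, 2 biological replicate cell samples were collected at each time point, but each time point has 1 column of values, and whether the samples were pooled is not given in the sources used here. Per the authors' notes beside the files, reads were mapped to the genome of strain CT-43. The mapper, the counting tool, their versions and the genome build are not given in the sources used here, nor whether counting used the strand or how reads shared between near-identical copies were assigned, so values of gene copies and of overlapping genes are uncertain.

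Values are RPKM, per the file headers: reads scaled to the length of the open reading frame and to the reads of the library, deposited in 1 table for 5529 chromosome genes and 1 for 665 plasmid genes. Symbols and products were taken from the same tables, which give a symbol for 1608 of 6194 genes. The plasmid table gives the start and end of each gene on its plasmid, and no positions of chromosome genes were used. The column sums differ, at 1860068.5, 2221022.8, 1639694.9 and 2958003.6 RPKM for the chromosome at 7, 9, 13 and 22 h and 300437, 467139, 239427 and 36757 for the plasmids. The deposited maps of mapped read frequency per base, a coverage signal for the chromosome and each plasmid, hold 40 columns in 10 maps without a header. No column could be given to a time point, so they were not analysed here and only the replicon lengths were read from them. Shares of coverage and coverage outside genes, which had been planned, are therefore not reported.

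On the plasmids, RPKM times gene length was a whole multiple of 1 step per column for 100% of values, within 0.01 read. The totals behind the columns are therefore 356614, 344816, 220320 and 1274050 reads at 7, 9, 13 and 22 h, and 1 read in a 1 kb gene was 2.80, 2.90, 4.54 and 0.785 RPKM. In the chromosome table most values have up to 6 digits, and 0.3% to 1.0% of these fit whole reads at the same totals. Values of 8 or more digits, 47, 65, 100 and 16 per library, did so in 93.6%, 92.3%, 95.0% and 81.2% of cases. The match asked for was finer than 6 digits can hold, and at most 60 reads were tried, so the shorter values could miss it by rounding alone. For most chromosome values this test thus cannot decide. The depth behind them is unknown, and no interval is given for them. The chromosome table holds no value between 0 and 2 RPKM, and genes that every cell uses are among its zeros, so such a gene is described as listed at 0 and no fold is given against it. Empty cells, 1, 4 and 1 at 7, 9 and 22 h, were treated as missing. Of 6194 genes, 4071 reached 10 RPKM in at least 1 library.

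The samples form 4 groups of 1 library, compared as 9 h against 7 h, 13 h against 9 h, 22 h against 13 h and 22 h against 7 h. The following choices were made before the data were examined. A log2 ratio with a pseudocount of 1 RPKM of at least 1 in size, a 2-fold difference, in genes with at least 10 RPKM in either library, was called higher or lower, with values as deposited. There is no spread between libraries to test against, so no p-value was computed. For 28 gene lists, defined by symbols or product words, the median log2 ratio over members with at least 10 RPKM in any library was placed among 10000 random lists of the same size drawn from 20 bins of mean log2(RPKM + 1). The higher and lower counts of a list cover its members with at least 10 RPKM in either library compared. Membership follows names alone, so a list can hold genes that serve other functions. A list for the thuringiensin cluster matched 0 genes. The time of the highest value, the share of summed RPKM on each replicon and the share of the 10 and 100 highest genes were also set then, as was the assumption of RPKM as the unit, which the values did not contradict.

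The genes named were set by a rule. It took the 8 largest log2 ratios in each direction per comparison among genes with a symbol or a product other than hypothetical or uncharacterized. To these it added all members of the toxin, thuringiensin, sporulation regulator and citric acid cycle lists and, for each other list, the 3 members with the highest mean RPKM, in all 164 genes. A further 52 genes, of which cspB2 and gap1 also meet the rule, were chosen after their values were seen. These are the plasmid genes Cry1Ia, Cry2Aa, pCT281.287, pCT127.076, pCT281.042, pCT83.062 and pCT281.285; and on the chromosome cspB1, cspB2, cspC, CT-43_CH4053, ptsI, gap1, gap2, sigB, general stress genes, the hut, nar, nir, aco, ilvC1, leu, purE, purF and purL genes, ctaE, qoxA, nuoC, gabT, tasA, cotD, cotM, cotY, collagen-like and amidase genes, CT-43_CH4802 and CT-43_CH1396.

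For plasmid genes, 95% intervals of counts are exact Poisson intervals, those of shares of reads are Clopper-Pearson intervals, and those of ratios are Clopper-Pearson intervals of the split of reads given the totals behind the columns. For genes with 0 reads, the upper limit given in text and plots is 3 reads. A count of reads in 2 libraries compares those libraries only. The work used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.

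The size rule was tested on simulated data for 9 h against 7 h with 2672 genes. These were the genes above 0 at 7 h, so genes listed at 0 there were left out. Depths were the totals behind the plasmid columns, and lengths of chromosome genes were drawn from plasmid genes. The true depth of the chromosome values is unknown, so the rates below hold for these settings only. It called 92.0% of genes raised 4-fold, 98.0% of those raised 8-fold, 80.0% of those at 0.25 of their level and 86.0% of those at 0.125. It also called 13.4% of 2472 unchanged genes and 4.0% of the 1313 with at least 100 RPKM. Counts of called genes can therefore hold low genes that counting error alone moves, at a rate not known for the chromosome. Of 200 lists of 40 unchanged genes, 5.5% lay outside the central 95% of percentiles. The use of 200 lists was chosen after a first simulated list had been seen.

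Alternatives planned were pseudocounts of 0.1 and 10 RPKM, no filter or a filter of 50 RPKM, a 4-fold rule, list members by symbol only, ratios of summed RPKM, and 3 scalings. These were equal sums over all genes, the median of ratios over 428 genes with at least 10 RPKM in every library, and equal sums without the 100 highest genes. Alternatives chosen after seeing the data were comparisons of genes above 0 in both libraries, each table alone, and shares of reads with and without cry1Ba, cry1Aa, Cry2Aa and pCT281.287. The 2 tables may have been normalized separately, so a level on a plasmid set against the chromosome rests on that being the same.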

Results

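Messenger RNA of Bacillus thuringiensis strain CT-43, a spore-forming soil bacterium that makes insecticidal protein crystals, was sequenced at 4 culture times. The culture grew in liquid GYS medium at 28 °C, and cells were taken at 7 h (mid-exponential phase), 9 h (early-stationary), 13 h (mid-stationary) and 22 h (late-stationary). Each time point is 1 library, so no difference between time points has a replicate check. Levels are in RPKM, reads scaled to gene length and to the reads of the library, for 5529 chromosome genes and 665 genes on 9 plasmids. The totals behind the plasmid columns, worked out from the values, were 356614 reads at 7 h, 344816 at 9 h, 220320 at 13 h and 1274050 at 22 h. The depth behind the chromosome columns is unknown. A value above 0 was listed for 2261, 2384, 2941 and 979 chromosome genes at 7, 9, 13 and 22 h, and 59.1%, 56.9%, 46.8% and 82.3% of chromosome genes were listed at 0. On the plasmids, 411, 419, 544 and 256 genes had at least 1 read. A gene is called higher or lower where its ratio on the log2(RPKM + 1) scale was at least 1 in size and its value reached 10 RPKM in either library. That scale understates the differences of low genes. A gene list's percentile is the place of its median among 10000 random lists of the same size and mean expression, and describes these libraries only. Genes outside the naming rule were chosen after their values were seen.

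The first comparison, 9 h against 7 h, sets early-stationary cells against mid-exponential cells. Regulators of sporulation went both ways at 9 h. The gene of the master regulator Spo0A, spo0A (CT-43_CH4185), had 744 RPKM at 7 h and 2319 at 9 h, and spo0F (CT-43_CH5376), whose product passes phosphate on toward Spo0A, had 224 and 773, while spo0B, for the next step of that relay, was lower with 70.3 and 34.5. The repressor gene sinR (CT-43_CH1212), which holds back biofilm and sporulation genes, was lower as well, with 530 and 61.3 RPKM, while sinI (CT-43_CH1213), the gene of its antagonist, had 219 and 1365. Genes for making nucleotides stood lower: purL (CT-43_CH0270) had 248 RPKM at 7 h and 31.2 at 9 h, and purF (CT-43_CH0271), the first enzyme of purine synthesis, 591 and 118. Of 2817 genes compared, 735 were higher, 774 lower and 1308 neither, with a median log2 ratio of -0.03. Of these, 287 were higher from a listed value of 0 and 189 lower to a listed value of 0. Rescaling each library to the same sum shifted every log2 ratio by -0.32 and moved the higher share of the called genes from 48.7% to 36.8%, with 515 higher and 885 lower. The median of ratios shifted them by -0.11. Across the sporulation regulators and sigma factors, 8 of 20 compared were higher, 4 lower and 8 neither (median 0.00, percentile 51.9).

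Nucleotide synthesis genes lay below their random lists at 9 h: of 30 members, 1 was higher, 24 lower and 5 neither, with a median of -1.76 at percentile 0. The kinase gene pyrH (CT-43_CH3824) had 955 RPKM at 7 h and 518 at 9 h, and pyrE (CT-43_CH3883), for pyrimidine synthesis, 776 and 211. Ribosomal protein genes, which set the capacity for protein synthesis, also lay below their random lists, with 3 of 55 higher, 20 lower and 32 neither and a median of -0.62 at percentile 0. The small-subunit gene rpsO (CT-43_CH3805) had 34966 and 20079 RPKM, whereas rpsF (CT-43_CH5515) had 10764 and 11216 and rplU (CT-43_CH4459) 21230 and 19457. Of 29 aminoacyl-tRNA synthetase genes compared, whose products load amino acids onto tRNA, 3 were higher, 10 lower and 16 neither (median -0.62, percentile 1.54). serS (CT-43_CH0012) had 2890 RPKM at 7 h and 970 at 9 h, gltX (CT-43_CH0084) had 304 and 178, and aspS (CT-43_CH4419) had 261 and 304. The glycolysis list had 0 members higher, 6 lower and 7 neither (median -0.98, percentile 0.24). The enolase gene eno (CT-43_CH5163) had 4845 and 2199 RPKM, tpiA (CT-43_CH5165) 2588 and 1317, and gap1 (CT-43_CH4602) 435 and 766. The gene gap2 (CT-43_CH5167), with the same product as gap1 but outside the list, had 5593 and 1626.

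Of 18 heat shock and Clp protease genes compared, which fold or clear damaged proteins, 0 were higher, 11 lower and 7 neither, with a median of -1.04 at percentile 0.05. The chaperonin genes groES (CT-43_CH0240) and groEL (CT-43_CH0241) had 6069 and 5455 RPKM at 7 h and 2721 and 1376 at 9 h, and clpX (CT-43_CH4486) had 1958 and 686. The oxidative and general stress list had 1 member higher, 9 lower and 6 neither (median -0.78, percentile 1.41). Its summed RPKM was not lower, with 22240 at 7 h and 22853 at 9 h. The general stress sigma factor gene sigB (CT-43_CH0939) had 323 RPKM at 7 h and 6.54 at 9 h. The superoxide dismutase genes sodA1 (CT-43_CH4291; 5562 and 9914 RPKM) and sodA2 (CT-43_CH5487; 11953 and 10028) and the general stress gene yugI (CT-43_CH4903; 828 and 905) were neither higher nor lower. Virulence genes of the kind run by the regulator PlcR had 1 member higher, 9 lower and 7 neither (median -1.07, percentile 0.33). The cytolysin gene alo (CT-43_CH5149) had 1124 and 510 RPKM, the enterotoxin gene CT-43_CH1743 had 1098 and 512, and the immune inhibitor gene inhA (CT-43_CH0595) 901 and 590. The gene of PapR, the peptide that switches PlcR on, was papR (CT-43_CH5389), listed at 0 at 7 h and at 938 RPKM at 9 h. Flagella and chemotaxis genes compared numbered 9, of which 0 were higher, 6 lower and 3 neither (median -0.75, percentile 2.11). The flagellin gene CT-43_CH1584 had 514 and 66.1 RPKM and the filament cap gene fliD (CT-43_CH1565) 68.6 and 6.29.

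Respiration genes went against this trend. In the respiratory chain list, 17 of 40 genes compared were higher at 9 h, 3 lower and 20 neither, with a median of 0.71 at percentile 99.9. The menaquinol-cytochrome reductase gene qcrA (CT-43_CH1449) had 6487 RPKM at 7 h and 13100 at 9 h, and ctaE (CT-43_CH3947), for a cytochrome oxidase subunit, 395 and 1507. qoxC (CT-43_CH0678) had 6348 and 4894 and qoxB (CT-43_CH0679) 2640 and 2103, both neither. Acetoin genes serve a neutral overflow product of sugar use that can be taken up again. This list had 5 members higher, 3 of them from a listed 0, 2 lower and 4 neither (median 1.12, percentile 99.6), and a median of 0.21 over members above 0 in both libraries. Its summed RPKM gave a log2 ratio of -0.99, since the high members alsS (CT-43_CH0836; 2487 and 760 RPKM) and alsD (CT-43_CH0837; 1070 and 367), for making acetoin, were lower. The butanediol dehydrogenase gene CT-43_CH0598 had 2964 and 1694. Of 18 extracellular protease and chitin degradation genes compared, 8 were higher, 5 lower and 5 neither (median 0.38, percentile 98.5). The higher genes included tasA (CT-43_CH1209; 33.4 and 314 RPKM), for a biofilm fibre, which the list took in by its symbol. The camelysin gene calY (CT-43_CH1211), for a surface protease, had 583 and 1690 RPKM, the bacillolysin gene CT-43_CH5102 had 746 and 1728, and the bacillolysin gene CT-43_CH0522 had 432 and 447. In the list for the GABA shunt and branched-chain acid breakdown, 2 were higher, 2 lower and 4 neither (median 0.66, percentile 94.6). The summed RPKM of this list went the other way, with 2709 at 7 h and 2164 at 9 h. There pdhC (CT-43_CH3976) had 1500 and 263 RPKM, bfmbB (CT-43_CH4173) 389 and 682, and yqiS (CT-43_CH4179) 165 and 328. Both pdhC and bfmbB entered this list by product words, not by symbol.

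The largest differences at 9 h were genes that crossed between 0 and a listed value. Besides papR, the 8 highest ratios among genes with a symbol or a product other than hypothetical belonged to the hydrolase gene CT-43_CH3085 (607 RPKM at 9 h), the AraC-family regulator gene CT-43_CH2724 (552), the stage 0 sporulation gene CT-43_CH1083 (549.9), the isochorismatase gene CT-43_CH3086 (462), the efflux accessory gene CT-43_CH0517 (449), the dehydratase gene CT-43_CH4375 (432) and the glyoxalase-family gene CT-43_CH3585 (430.4), each listed at 0 at 7 h. The 8 lowest ratios in that set belonged to genes listed at 0 at 9 h. These were the cytoplasmic protein gene CT-43_CH5455 (613 RPKM at 7 h), the methylglyoxal synthase gene mgsA (CT-43_CH1460; 265), ecsC (CT-43_CH4656; 262), the AraC-family gene CT-43_CH3200 (262), the PbsX-family gene CT-43_CH1193 (257), the murein hydrolase export gene CT-43_CH5160 (254), the iojap-family gene CT-43_CH4347 (239.9) and the surface protein gene CT-43_CH0760 (215).

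The second comparison, 13 h against 9 h, sets mid-stationary cells against early-stationary cells. Genes of sigma factors that act in the developing spore stood higher at 13 h. The genes of the mother-cell sigma factors sigE (CT-43_CH3905) and sigK (CT-43_CH4356) were listed at 0 at 7 and 9 h and at 396 and 2036 RPKM at 13 h. For the forespore, sigG (CT-43_CH3904) was listed at 0 and then at 2905, and sigF (CT-43_CH4080) had 82.1 and 434. Some early regulators were lower, such as spo0A at 2319 and 201 RPKM and the transition repressor gene abrB (CT-43_CH0032) at 3352 and then listed at 0. The genes of the insecticidal crystal proteins were higher too, with cry1Ba at 62.1 and 26134 RPKM. Of 3782 genes compared, 1897 were higher, 1012 lower and 873 neither, with a median log2 ratio of 1.01. The higher genes included 1023 that were listed at 0 at 9 h, and 355 of the lower were listed at 0 at 13 h. Shifts of the log2 ratios were 0.52 with equal sums, 0.24 with the median of ratios and -0.47 with the sum without the 100 highest genes, and the higher share of the called genes, 65.2%, moved by less than 10 points under each of them.

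The crystal toxin genes sit on the plasmids pCT127 and pCT281, where whole reads could be worked out, so each fold below has an exact conditional (Clopper-Pearson) 95% interval. These intervals, and the floor of 3 reads used for genes without a read, cover counting error only, and they compare the libraries, not the conditions. All 4 members of the toxin list were higher at 13 h than at 9 h (median 5.32, percentile 99.1). cry1Ba (pCT127.021, bases 25432 to 29118 of pCT127, reverse strand) had 43.4, 62.1, 26134 and 6853 RPKM at 7, 9, 13 and 22 h, from 57, 79, 21229 and 32193 reads. Its 13 h value was 421-fold its 9 h value (interval 337 to 531) and held 9.64% of all reads behind the 13 h column. cry1Aa (pCT281.277, bases 266970 to 270500 of pCT281, forward strand) had 7.94, 18.9, 6362 and 479 RPKM, and was 337-fold higher at 13 h than at 9 h (224 to 532). cry2Ab (pCT281.272, bases 257224 to 259125) had 5.90, 18.3, 95.5 and 7.84 RPKM and was 5.22-fold higher (2.68 to 10.9). The vegetative insecticidal gene Vip3V (pCT281.268, bases 252117 to 254486) had 2.37, 12.2 and 38.3 RPKM and then 0 reads at 22 h, where 3 reads would be 0.994 RPKM. It was 3.13-fold higher at 13 h than at 9 h (1.40 to 7.49).

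From 7 h to 9 h the size rule called 3 of the 4 toxin genes higher at 9 h and 1 neither (median 1.32, percentile 95.2). For cry2Ab the ratio of 3.10 had an interval of 0.940 to 13.2, so a difference was not detectable at this depth, and Vip3V rested on 2 and 10 reads (ratio 5.17, 1.10 to 48.5). cry1Aa was 2.38-fold higher (1.09 to 5.60) and cry1Ba 1.43-fold (1.01 to 2.05). These readings hold as deposited. The log2 ratios shift by -0.32 with equal sums, -0.11 with the median of ratios and -0.03 with the sum without the 100 highest genes. The interval of cry1Ba then includes 1 under each scaling, and those of cry1Aa and Vip3V do so with equal sums. Outside the list, and chosen after their values were seen, Cry2Aa (pCT281.286, bases 278386 to 280287) had 10.3, 27.4, 7553 and 42.5 RPKM and was 275-fold higher at 13 h than at 9 h (174 to 465). Its neighbour pCT281.287 (bases 280384 to 281142), for an uncharacterized protein upstream of the crystal gene, had 20230.5 RPKM at 13 h from 3383 reads, against 2 reads at 9 h (ratio 2647, 732 to 21869). Cry1Ia (pCT281.278, bases 271007 to 273166) had 76.6, 59.1 and 162 RPKM and 0 reads at 22 h.

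**Figure D1:**
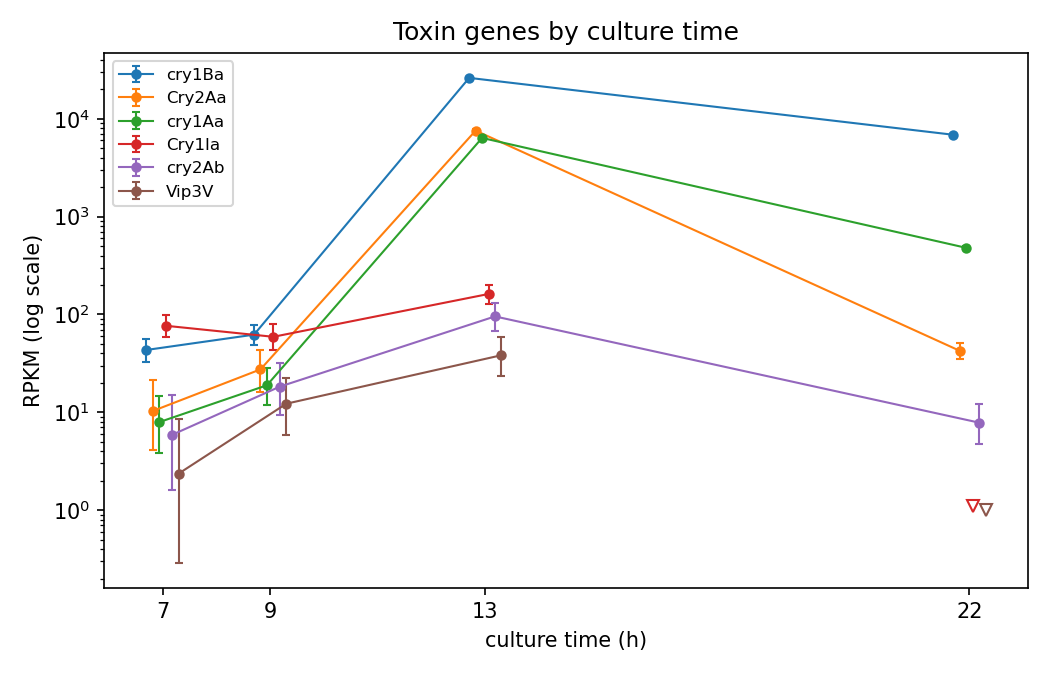
RPKM on a log axis against culture time in hours for 6 insecticidal toxin genes, 1 library per time point. Circles are values with 95% exact Poisson intervals and open triangles are the level of 3 reads for genes with 0 reads; cry1Ba, cry1Aa and Cry2Aa stand at 26134, 6362 and 7553 RPKM at 13 h, and the lower 22 h value of cry1Ba turns higher (log2 ratio 0.33) with the median of ratios.

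Lists of structural genes of the spore lay above their random lists at 13 h. Small acid-soluble spore proteins coat the DNA of the spore, and all 14 of their genes were listed at 0 at 7 and 9 h and higher at 13 h (median 10.87, percentile 100). The highest was ssp (CT-43_CH0446) with 38954 RPKM, while ssp (CT-43_CH1940) had 4758 and sasP1 (CT-43_CH0827) 4742. Of 21 coat and exosporium genes compared, which build the outer shells of the spore, 19 were higher, 18 of them from a listed 0, 1 lower and 1 neither (median 10.66, percentile 100). The 3 coat genes above 0 in both libraries had a median of 0.40. The lower member, tasA (CT-43_CH1209; 314 and 57.9 RPKM), is among these 3. It is a gene for a biofilm fibre that entered the list by product words. cotZ2 (CT-43_CH1160) had 18571 RPKM, the collagen-like exosporium gene CT-43_CH1145 had 17492 and cotE (CT-43_CH3713) 11368, each listed at 0 at 9 h. Stage II and III sporulation genes, for engulfing the forespore, had 18 members higher, 17 of them from a listed 0, 1 lower and 1 neither (median 8.46, percentile 100), and a median of 0.69 over the 3 above 0 in both libraries, with spoIIIAF (CT-43_CH4202) at 28572 RPKM and spoIIQ (CT-43_CH5322) at 6272. Stage IV to VI genes had 23 higher, 19 of them from a listed 0, 3 lower and 6 neither (median 4.92, percentile 99.99). Their sum went the other way, with a log2 ratio of -0.52, since spoVG (CT-43_CH0043), a regulator active before sporulation, had 21063 RPKM at 9 h and 1033 at 13 h. spoVS2 (CT-43_CH3719) had 6601 and 4720.0 and spoVS (CT-43_CH2092) 2428 and 2147. All 37 germination genes compared, whose products let the spore sense nutrients and reawaken, were higher (median 6.20, percentile 100), 36 of them from a listed 0. These included gerQ (CT-43_CH5431; 13838 RPKM) and gerPE (CT-43_CH1078; 1697). The cortex hydrolase gene cwlJ2 (CT-43_CH5430) had 13939.7 RPKM and the phage protein gene CT-43_CH4970 had 19030.3, both from a listed 0.

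Across the list of 35 sporulation regulators and sigma factors, 14 were higher at 13 h, 10 of them from a listed 0, 7 lower and 9 neither (median 0.79, percentile 67.5). The mother-cell regulator gene spoIIID (CT-43_CH5320) was listed at 0 and then at 6777 RPKM, spoIIGA (CT-43_CH3906), whose product activates sigma E, at 931, and the forespore regulator genes rsfA at 7714 (CT-43_CH3923), 2216 (CT-43_CH5425) and 209 (CT-43_CH4417). The anti-sigma gene spoIIAB (CT-43_CH4081) had 213 and 851 RPKM and its partner spoIIAA (CT-43_CH4082) 659 and 1063, the latter neither. The stage 0 genes CT-43_CH2313 (106 and 913 RPKM) and CT-43_CH1265 (44.9 and 101) and the kinase gene kinD (CT-43_CH1266; 0 and 75.8) were higher. Lower were abrB (CT-43_CH1953; 1122 and then 0), abrB (CT-43_CH2405; 11.3 and then 0), kinC (CT-43_CH2209; 405 and 20.002), spo0F (773 and 185) and sigH (CT-43_CH0090; 658 and 189.8). Neither call was given to spo0B (CT-43_CH4456; 34.5 and 51.7 RPKM), spoVT (CT-43_CH0049; 363 and 674), soJ (CT-43_CH5521; 163 and 189), spo0J (CT-43_CH5520; 213 and 341), spo0J (CT-43_CH5522; 115 and 122), sinI (1365 and 837), sinR (61.3 and 41.3) and CT-43_CH1083 (549.9 and 506). A second sigF copy (CT-43_CH4975) had 22.8 RPKM at 13 h only. A further sigF (CT-43_CH0620), abrB (CT-43_CH1827), the spo0E-like gene CT-43_CH1553 and the stage 0 gene CT-43_CH4999 were listed at 0 in all 4 libraries.

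The citric acid and glyoxylate cycle list, for burning acetate, had 1 member higher, 12 lower and 4 neither (median -2.90, percentile 0.04). The malate dehydrogenase gene mdh (CT-43_CH4612) had 5120.0 RPKM at 9 h and 36.2 at 13 h, sucD (CT-43_CH3835) had 3177 and 97.9, sucC (CT-43_CH3836) 1402 and 83.13, and citC (CT-43_CH4613) 2215 and 162. Also lower were acnA (CT-43_CH3562; 3468 and 603), citZ (CT-43_CH4614; 2245 and 275), odhB (CT-43_CH1191; 3406 and 445), fumA (CT-43_CH0410; 343 and 68.8), malS (CT-43_CH1676; 14.7 and 3.31) and the succinate dehydrogenase genes sdhA (CT-43_CH4536; 729 and 96.9), sdhB (CT-43_CH4535; 1480.4 and 67.0) and sdhC (CT-43_CH4537; 1396 and 109). The isocitrate lyase gene aceA (CT-43_CH1064), which starts the glyoxylate bypass, was the member that was higher, with 177 and 781 RPKM. aceB (CT-43_CH1063) had 163 and 214, sucA (CT-43_CH1192) 1519 and 997, fumC (CT-43_CH1645) 102 and 101, and the related gene CT-43_CH3546 575 and 1133. From 7 h to 9 h this list had 3 higher, 1 lower and 13 neither (median -0.07, percentile 30.4), with aceA at 40.6 and 177 and aceB at 29.8 and 163. ATP synthase genes had 0 higher, 7 lower and 3 neither (median -1.26, percentile 10.0), with atpC (CT-43_CH5344) at 1583 and 84.8 RPKM, atpD (CT-43_CH5345) at 1152 and 286, and atpG (CT-43_CH5346) at 931 and 206. Genes for storing polyhydroxybutyrate, a carbon reserve, had 1 higher, 3 lower and 2 neither (median -1.18, percentile 35.1). The synthase gene phaC (CT-43_CH1248) had 2313 and 235 RPKM, while the granule gene phaP (CT-43_CH1244; 3339 and 3363) and phaQ (CT-43_CH1245; 990.1 and 1049) were neither.

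The amino acid synthesis list had 42 members higher, 9 lower and 11 neither (median 2.27, percentile 99.96), among them ilvC1 (CT-43_CH1328; 9.37 and 793 RPKM) and leuB (CT-43_CH1330; 93.5 and 1209) for branched-chain amino acids. Its highest members, alsS, glnA (CT-43_CH3641; 1335 and 85.2) and metE (CT-43_CH4008; 651 and 98.4), were lower. Nucleotide synthesis had 14 higher, 4 lower and 12 neither (median 0.71, percentile 82.9), with the dihydroorotase gene CT-43_CH0437 at 8.26 and 1172 RPKM. Acetoin breakdown genes acoA (CT-43_CH2766; 9.48 and 997) and acoB (CT-43_CH2765; 12.2 and 1208) were among 8 of 14 acetoin genes that were higher (3 lower, 3 neither, median 1.24, percentile 73.0), while alsS and alsD were listed at 0. The heat shock list had 10 higher, 3 lower and 7 neither (median 1.29, percentile 99.1), with groES at 2721 and 21087 RPKM and groEL at 1376 and 5444. The stress list had 10 higher, 5 lower and 3 neither (median 1.78, percentile 98.4), but its median was -0.12 with members by symbol only. A catalase gene (CT-43_CH4802) was listed at 0 and then at 2466 RPKM, whereas sodA1 and sodA2 had 9914 and 10028 RPKM at 9 h and 572 and 258 at 13 h, and the list's summed RPKM gave a log2 ratio of -1.35.

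Ribosomal protein genes had 1 higher, 32 lower and 22 neither (median -1.11, percentile 28.2). PlcR-type virulence genes had 2 higher, 11 lower, 6 of them to a listed 0, and 3 neither (median -2.57, percentile 0.05), with alo, papR and CT-43_CH1743 listed at 0 and inhA at 18.9 RPKM. The respiratory chain list had 16 higher, 14 lower and 13 neither (median -0.03, percentile 42.6), with nuoC (CT-43_CH5338) at 54.7 and 431 RPKM but qcrA at 13100 and 727. DNA replication and division genes had 14 higher, 18 lower and 13 neither (median -0.15, percentile 4.68), with the primase gene dnaG (CT-43_CH4309) at 1098 and 402 RPKM and the septum-site gene minC (CT-43_CH4464) at 8062 and 195. Iron uptake genes had 14 higher, 9 of them from a listed 0, 3 lower and 2 neither (median 1.54, percentile 23.3), with CT-43_CH0536 at 22.8 and 58.5 RPKM, CT-43_CH0537 at 25.1 and 39.5, and bacA (CT-43_CH2265) for a siderophore at 11.1 and 23.1. Phage genes, of which 22 of 124 were compared, had 16 higher, 11 of them from a listed 0, 2 lower and 4 neither (median 2.16, percentile 58.2). CT-43_CH2574 was listed at 0 and then at 1283 RPKM, whereas the antiholin-like gene lrgB (CT-43_CH5480) had 8170.1 and 16.4. Mobile element genes had 38 higher, 20 of them from a listed 0, 4 lower and 23 neither (median 1.41, percentile 69.9). Among them xerC (CT-43_CH3831), for a site-specific recombinase, had 514 and 1395 RPKM, the transposase gene pCT281.240 (bases 223765 to 224883) had 4232 and 576, and the group II intron gene pCT127.077 (bases 81109 to 83031) 1430 and 1551. Flagella and chemotaxis genes had 7 higher, 2 lower and 3 neither (median 0.74, percentile 30.7), with fliD at 6.29 and 202 and the chemotaxis receptor gene CT-43_CH0479 at 0 and 632. Besides the abrB genes, the 8 lowest ratios among genes with a symbol or a product other than hypothetical belonged to genes then listed at 0. They were the EMG2 protein gene CT-43_CH4311 (12899 RPKM at 9 h), the acetyltransferase gene CT-43_CH1162 (5093), the sugar uptake gene celA2 (CT-43_CH5238; 2694), the ArsR-family gene CT-43_CH0533 (2583), the ribosome-binding factor gene rbfA (CT-43_CH3808; 1209.5) and the oligopeptide transport gene oppF (CT-43_CH1120; 1154).

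**Figure D2:**
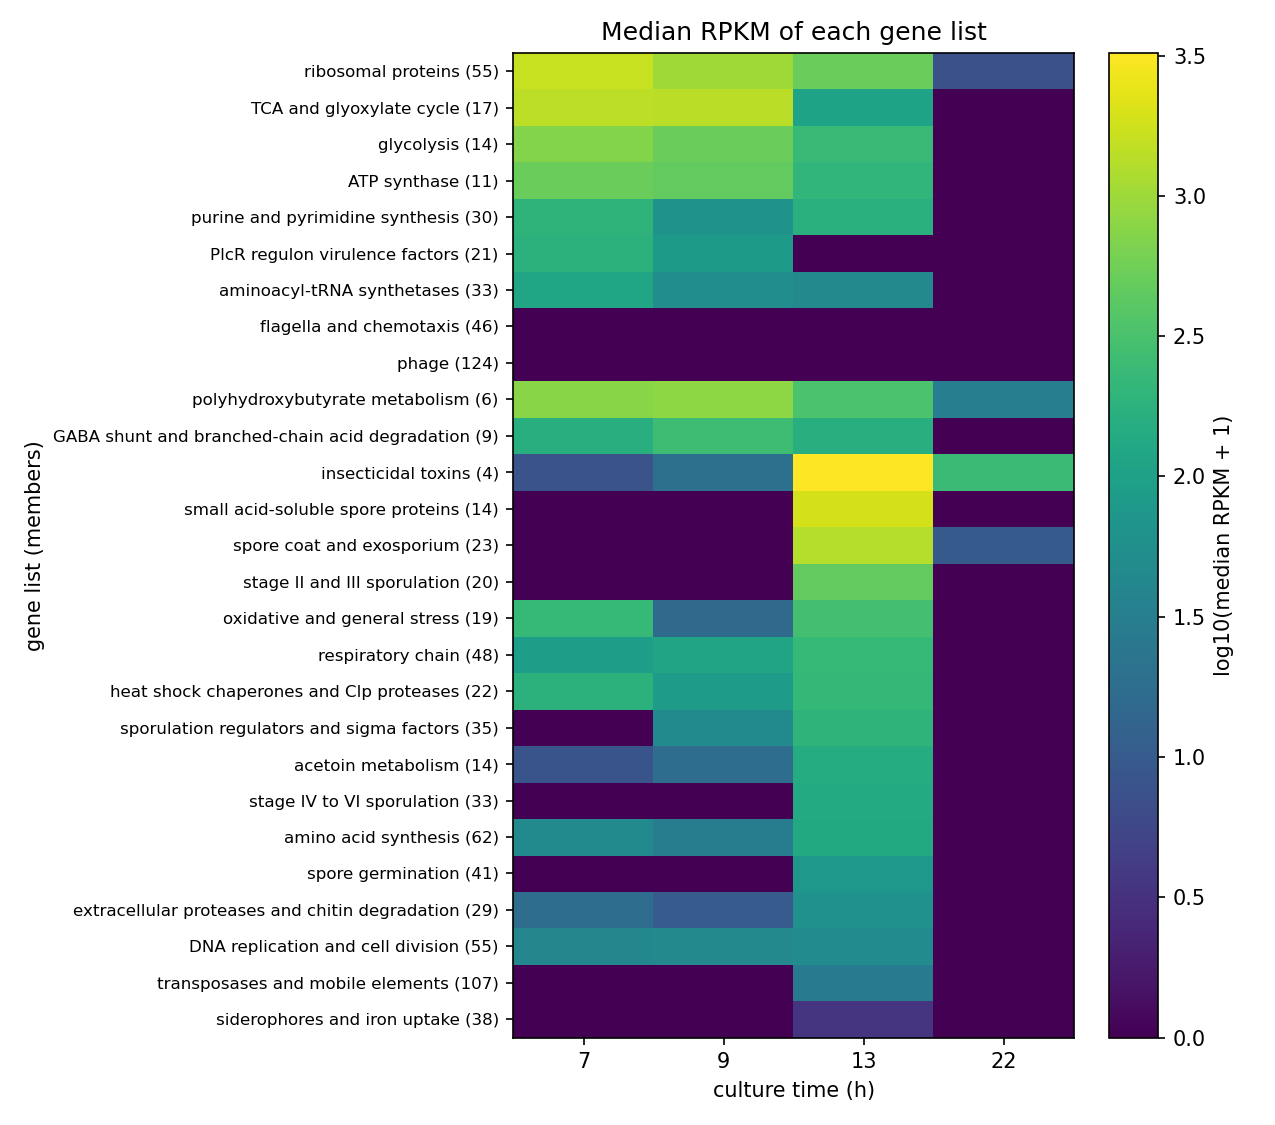
Median RPKM of each gene list at 7, 9, 13 and 22 h, with lists down the side and the number of members in brackets; colour gives log10(median RPKM + 1), and lists are ordered by the time of their highest median. The ribosomal protein median is 1627 RPKM at 7 h and 6.31 at 22 h, and the median of small acid-soluble spore protein genes is 0 at 7 and 9 h and 1921 at 13 h.

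The third comparison, 22 h against 13 h, sets late-stationary cells against mid-stationary cells. At 22 h a small set of coat genes held very high values. The genes of the coat proteins CotG, cotG (CT-43_CH1986), and CotH, cotH (CT-43_CH1987), had 78.4 and 147 RPKM at 13 h and 230911 and 87242 at 22 h. The coat gene spoB (CT-43_CH0332) had 100.2 and 42004, and gerE (CT-43_CH4520), the last regulator of the mother cell, was listed at 0 and then at 2288. Other spore genes were lower, such as cotE (11368 and 451) and ssp (CT-43_CH0446; 38954 and then listed at 0). Of 3574 genes compared, 275 were higher, 3148 lower and 151 neither, with a median log2 ratio of -5.90, and 2366 of the lower genes were listed at 0 at 22 h. The size of the lower share depends on the scaling. The log2 ratios shifted by -0.67 with equal sums, by 2.26 with the median of ratios and by 3.65 with the sum without the 100 highest genes. Under the last, 688 genes were higher and 2373 lower, and the higher share of the called genes was 22.5% against 8.0%.

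Coat and exosporium genes parted into sets at 22 h, with 7 higher, 13 lower and 2 neither of 22 compared (median -6.40, percentile 21.9). The members above 0 in both libraries had a median of 0.89 and the list's summed RPKM a log2 ratio of 2.17, both in the other direction. Higher members included cotD (CT-43_CH1484; 159 and 5424 RPKM), cotM (CT-43_CH3567; 134 and 3498) and cotY (CT-43_CH1156; 2001 and 6693), while CT-43_CH1145 had 17492 and 17854 and cotZ2 18571 and 153. Small acid-soluble spore protein genes had 0 higher and 14 lower, 9 of them to a listed 0 (median -9.65, percentile 0). Stage II and III genes had 0 higher and 20 lower, 15 of them to a listed 0 (median -8.46, percentile 0.04), with spoIIIAF and spoIIQ listed at 0. Stage IV to VI genes had 2 higher, 29 lower, 23 of them to a listed 0, and 1 neither (median -6.20, percentile 1.68), and spoVS was a higher one at 2147 and 7596 RPKM. Germination genes had 2 higher and 37 lower, 30 of them to a listed 0 (median -5.80, percentile 0.12), with gerQ at 13838 and 7.38 RPKM. The regulator list had 1 higher, 25 lower, 18 of them to a listed 0, and 1 neither (median -7.12, percentile 1.45). spoIIID had 6777 and 216 RPKM, sigK 2036 and 90.1, rsfA (CT-43_CH3923) 7714 and 34.4, and kinC 20.002 and 19.9, while sigE, sigF, sigG, spo0A, sinR and sinI were listed at 0 and spo0F had an empty cell.

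The toxin list had 0 members higher and 4 lower at 22 h than at 13 h (median -3.59, percentile 74.8), but this direction depends on the scaling for cry1Ba and cry2Ab. cry1Ba was 3.81-fold lower (3.75 to 3.88), and its log2 ratio of -1.93 became 0.33 with the median of ratios and 1.72 with the sum without the 100 highest genes. cry2Ab was 12.2-fold lower (6.89 to 22.3), and its log2 ratio became 0.05 under the last scaling. cry1Aa (pCT281.277) was 13.3-fold lower (12.6 to 14.0), but its log2 ratio was -0.08 under that scaling, and Cry2Aa was 178-fold lower (146 to 218). cry1Ba still held 2.53% of all reads behind the 22 h column.

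Genes outside the spore lists also had high values at 22 h. The spore appendage gene CT-43_CH2337, for filaments on the spore surface, was listed at 0 and then at 97529 RPKM, and its neighbour in the list, the division gene divIC2 (CT-43_CH2338), had 110.5 and 154350. This gene turned the summed RPKM of the replication and division list to a log2 ratio of 4.52, although 1 member was higher and 41 lower (median -5.97, percentile 20.6). Besides CT-43_CH2337 and cotG, the 8 highest ratios among genes with a symbol or a product other than hypothetical belonged to a second spoB (CT-43_CH0333; 11368 RPKM at 22 h), the cell wall peptidase gene CT-43_CH2657 (3382), the collagen-like genes CT-43_CH1385 (3348) and CT-43_CH3780 (3051), the oxidase gene CT-43_CH3180 (3182) and the arsenical pump gene CT-43_CH5253 (2939.6), each listed at 0 at 13 h. The 8 lowest ratios in that set were of genes then listed at 0. Besides ssp (CT-43_CH0446), spoIIIAF, CT-43_CH4970, cwlJ2 and spoIIQ, they were the cold shock gene cspB2 (CT-43_CH3483; 44963 RPKM at 13 h), the acyl carrier gene acpP (CT-43_CH3850; 7854) and the ferredoxin gene fer (CT-43_CH1410; 6494).

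Most members of the lists for growth and metabolism were lower at 22 h, as were 3148 of all 3574 genes, and many of them were listed at 0 there. Ribosomal protein genes had 0 higher, 53 lower and 2 neither (median -5.995, percentile 12.7), with 14 listed at 0. Amino acid synthesis had 2 higher, 57 lower and 1 neither (median -6.96, percentile 0.06), but 50 of the lower were listed at 0 and members above 0 in both libraries had a median of -1.28. Nucleotide synthesis had 1 higher, 28 lower and 1 neither (median -7.27, percentile 0.51), all 28 to a listed 0, and the 2 members above 0 in both had a median of 0.90. The respiratory chain had 0 higher, 41 lower, 30 of them to a listed 0, and 2 neither (median -7.46, percentile 0.31). Aminoacyl-tRNA synthetases had 1 higher, 25 lower, 15 of them to a listed 0, and 3 neither (median -3.77, percentile 98.2), the citric acid cycle 0 higher and 16 lower (percentile 55.5), and ATP synthase 1 and 10 (percentile 25.0). Single genes that were lower here as deposited but higher on the log2 scale with the sum without the 100 highest genes were spoVT (1.12), CT-43_CH0517 (2.51), phaQ (1.25), glnA (2.24), rplU (0.43), sdhB (0.22), citZ (0.63), atpC (2.28) and soJ (0.99).

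The fourth comparison, 22 h against 7 h, sets the last library against growing cells. Ribosomal protein genes, the mark of growth, were all lower: 55 of 55, with a median of -7.91 at percentile 2.09 and 14 listed at 0. rpsO had 34966 RPKM at 7 h and 20.5 at 22 h, rpsF 10764 and 43.5, and rplU 21230 and 387. Coat and exosporium genes were mostly the opposite, with 11 higher and 3 lower of 14 compared (median 3.50, percentile 100). All 11, led by cotG, cotH and spoB, were listed at 0 at 7 h. All 3 lower ones, among them tasA, were listed at 0 at 22 h, so no compared member was above 0 in both libraries. Of 2841 genes compared, 459 were higher (372 from a listed 0), 2277 lower (1723 to a listed 0) and 105 neither, with a median log2 ratio of -5.68. The log2 ratios shifted by -0.47 with equal sums, 2.39 with the median of ratios and 3.16 with the sum without the 100 highest genes, and the last gave 789 higher and 1868 lower, a higher share of 29.7% against 16.8%.

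The 8 highest ratios at 22 h against 7 h among genes with a symbol or a product other than hypothetical were those of cotG, divIC2, CT-43_CH2337, cotH, the collagen-like gene CT-43_CH2359 (44219 RPKM), spoB (CT-43_CH0332), the spore-specific cell wall amidase gene CT-43_CH2172 (20134.7) and CT-43_CH1145, each listed at 0 at 7 h. The 8 lowest in that set were of genes listed at 0 at 22 h and high at 7 h. They were cspB2 (370299 RPKM), the ribosome hibernation gene yfiA (CT-43_CH5217; 40502), acpP (16185), fer (14259), lrgB (12157), sodA2 (11953), spoVG (11646) and the cold shock gene cspD (CT-43_CH4884; 8468). The citric acid cycle had 0 higher and 17 lower, 9 of them to a listed 0 (median -7.05, percentile 23.8). Glycolysis had 1 higher and 12 lower, 10 of them to a listed 0 (median -9.12, percentile 0.84), and its 3 members above 0 in both libraries had a median of -4.17. gap1, for a glyceraldehyde phosphate dehydrogenase, was the member of that list that was higher, with 435 and 1358 RPKM. The list took in gap1 by its symbol and left out gap2 (CT-43_CH5167), which has the same product. gap2 had 5593 RPKM at 7 h and was listed at 0 at 22 h. By gene number gap2 lies close to tpiA and eno of this list, and like them it had a lower value at 9 h than at 7 h, while gap1 had a higher one. The rise of gap1 may therefore not speak for glycolysis. Which of these genes serves glycolysis was not tested. PlcR-type virulence genes had 0 higher and 15 lower, 13 of them to a listed 0 (median -7.50, percentile 0.06). Of the toxin genes, cry1Ba was 158-fold higher at 22 h than at 7 h (122 to 209) and cry1Aa 60.3-fold (32.8 to 126). The cry2Ab ratio of 1.33 had an interval of 0.442 to 5.37, so as deposited a difference was not detectable at this depth. That reading depends on the scaling. Every log2 ratio shifts by 2.39 with the median of ratios and by 3.16 with the sum without the 100 highest genes, which puts this interval above 1. phaP, phaQ, spoVT and aspS were lower as deposited but had log2 ratios of 1.01, 1.48, 0.98 and 0.56 with the sum without the 100 highest genes.

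The time of the highest value was set for genes that reached 10 RPKM and whose highest value, with 1 RPKM added, was at least 2-fold their lowest. All 4 toxin genes (cry1Ba and cry2Ab as deposited but not with the sum without the 100 highest genes), all 14 small acid-soluble spore protein genes, 37 of 39 germination genes and 19 of 20 stage II and III genes had their highest value at 13 h. Coat and exosporium genes had it at 13 h in 13 cases and at 22 h in 8. Ribosomal protein genes had it at 7 h in 42 of 55 cases and nucleotide synthesis genes in 16 of 30, whereas 14 of 45 replication and division genes had it at 7 h and 17 at 13 h, and 15 of 62 amino acid synthesis genes at 7 h and 44 at 13 h. Among 4061 genes it fell at 7 h for 955, at 9 h for 799, at 13 h for 2042 and at 22 h for 265, and with the median of ratios 507 genes were highest at 22 h. On the plasmids the numbers were 68, 100, 368 and 17 of 553 genes.

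The plasmid genes' share of all reads behind the plasmid columns was 7.29% (Clopper-Pearson 95% interval 7.21 to 7.38) at 7 h, 10.6% (10.5 to 10.7) at 9 h, 22.7% (22.5 to 22.9) at 13 h and 3.62% (3.59 to 3.65) at 22 h. Without cry1Ba, cry1Aa, Cry2Aa and pCT281.287, left out after their values were seen, the shares were 7.3%, 10.6%, 9.2% and 0.9%. The short genes pCT281.042, pCT127.076 and pCT83.062 stayed in. They held 3.01%, 2.03% and 1.08% of all reads at 9 h, and 0.301%, 0.366% and 0.01% at 13 h. Shares without these short genes as well were not computed. The fall of pCT281.042, from 3.01% to 0.301%, was larger than the fall from 10.6% to 9.2% without the 4 genes. The plasmid genes other than the 4 and these short ones thus held a larger share at 13 h than at 9 h in these libraries. The higher share at 13 h therefore did not rest on the 4 genes alone, although the short genes were picked after their values were seen. The share of summed RPKM over both tables was 13.9%, 17.4%, 12.7% and 1.2%, so from 9 h to 13 h the measures went in opposite directions. The 2 tables may have been normalized separately, which bears on any share that sets plasmids against the chromosome. pCT127, with cry1Ba, held 3.06%, 3.11%, 11.5% and 2.73% of reads, and pCT281, with the other crystal genes, 1.36%, 4.92%, 9.00% and 0.492%. pCT83 went from 1.82% at 7 h to 1.69%, 0.444% and 0.069%. Single short genes of unknown function, chosen after their values were seen, set much of the early share. pCT127.076 (bases 80684 to 80806) had 162755, 165188, 29779 and 6994 RPKM, and its 22 h value was lower than its 13 h value as deposited and with equal sums, but higher with the median of ratios (log2 ratio 0.17) and with the sum without the 100 highest genes (1.56). pCT281.042 (bases 35617 to 35781) had 19289, 182232 and 18265 RPKM and 0 reads at 22 h, and pCT83.062 (bases 49576 to 49911) 41829, 32134 and 297 RPKM and 0 reads.

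**Figure D3:**
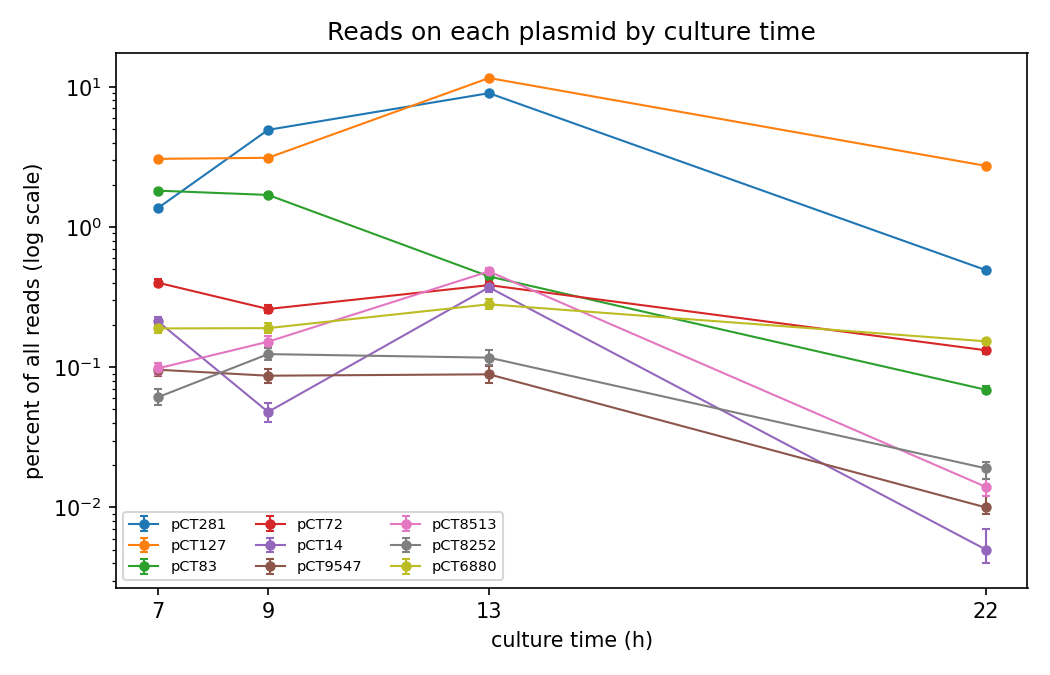
Percent of all reads on each of 9 plasmids, on a log axis, against culture time in hours, with 95% exact binomial intervals and 1 library per time point. pCT127 and pCT281 stand at 11.5% and 9.00% at 13 h, and pCT83 goes from 1.82% at 7 h to 0.069% at 22 h.

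The part of the summed RPKM held by the highest genes differed by time, as did the highest gene. Across both tables the 10 highest genes held 41.6%, 50.6%, 15.7% and 82.2% at 7, 9, 13 and 22 h, and the 100 highest held 67.1%, 73.1%, 46.7% and 97.3%. The cold shock gene cspB2, whose family binds RNA in the cold and in growing cells, was highest at 7 h (370299 RPKM, 17.1%) and 9 h (512020 RPKM, 19.0%). Its relative cspC (CT-43_CH5219) was highest at 13 h with 48641 RPKM, against 410.1, 343 and 7.77 at 7, 9 and 22 h. At 22 h the hypothetical protein gene CT-43_CH4053 had 1340000 RPKM, 44.7% of the sum, against 457 at 13 h and a listed 0 before. Beside it in the list, ptsI (CT-43_CH4054), for the first enzyme of sugar uptake by phosphotransfer, had 732, 674, 160 and 299960 RPKM. The pts genes listed next did not share this 22 h value. ptsH1 (CT-43_CH4055) was highest at 13 h with 639 RPKM and ptsG (CT-43_CH4056) at 7 h with 487. Whether the ptsI value holds reads from CT-43_CH4053 was not tested.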

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

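Comparisons of genes or list members above 0 in both libraries, each table alone, and shares of reads with and without crystal locus genes, were chosen after seeing the data. No paired analysis was possible because each time point has 1 library. Of the values under alternatives, 136 counts and shares stayed the same and 52 moved. A count stayed if it lay within 1.5 times its main value, and a plasmid share only if it was equal to 1 decimal. Ratios of genes and list medians stayed if within 1.5-fold of their main value. Named genes gave 2358 values within their bounds, 1765 that moved and 28 that reversed, and list medians gave 650, 396 and 8. A reversal is a change of sign, counted only where the main log2 ratio or median was at least 1 in size. Sign changes of smaller list medians are therefore not among the 8, and smaller gene ratios were not varied. Values in the order higher and lower are counts of genes. The cause of these differences was not tested, except where the alternative leaves out genes by its own construction.

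A 4-fold rule gave 404 and 367 genes at 9 h against 7 h, against 735 and 774. A filter of 50 RPKM gave 283 higher at 22 h against 7 h, against 459. With genes above 0 in both libraries, 448 were higher at 9 h against 7 h, and the counts were 874 and 657 at 13 h against 9 h, 90 and 782 at 22 h against 13 h, and 87 and 554 at 22 h against 7 h. Plasmids alone, a smaller set, gave 124 and 82, 338 and 81, 15 and 479, and 40 and 273. The median of ratios gave 471 higher at 22 h against 13 h, against 275, and 507 genes highest at 22 h, against 265. The sum without the 100 highest genes gave 688 higher at 22 h against 13 h and 789 at 22 h against 7 h.

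The plasmid share of summed RPKM without the 10 highest genes was 7.6, 6.6, 10.3 and 6.9% at 7, 9, 13 and 22 h, against 13.9, 17.4, 12.7 and 1.2%. As a share of reads it was 7.3, 10.6, 22.7 and 3.6%, and without cry1Ba, cry1Aa, Cry2Aa and pCT281.287 7.3, 10.6, 9.2 and 0.9%.

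As deposited, list medians above 1 and below -1 numbered 2 and 3 at 9 h against 7 h, 13 and 5 at 13 h against 9 h, 0 and 27 at 22 h against 13 h, and 2 and 19 at 22 h against 7 h. At 9 h against 7 h the number above 1 was 0 with a pseudocount of 10 RPKM and 1 with a filter of 50 RPKM, with equal sums, with members by symbol only and with summed RPKM. The number below -1 was 1 with no filter on low values, 6 with equal sums, 5 with members by symbol only, 5 with summed RPKM and 5 with only members above 0 in both libraries. At 13 h against 9 h the number below -1 was 2 with equal sums, 3 with the median of ratios and 8 with summed RPKM, and the number above 1 was 6 with only members above 0 in both libraries. The number above 1 was 2 at 22 h against 13 h with summed RPKM. At 22 h against 7 h it was 1 with members by symbol only, 5 with summed RPKM and 1 with only members above 0 in both libraries.

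With summed RPKM, acetoin metabolism reversed to -0.99 at 9 h against 7 h, stage IV to VI sporulation to -0.52 and the stress list to -1.35 at 13 h against 9 h, and the coat list to 2.17 at 22 h against 13 h. DNA replication and cell division reversed to 4.52 at 22 h against 13 h and 3.59 at 22 h against 7 h. The stress list was -0.12 at 13 h against 9 h with members by symbol only, and the coat list 0.89 at 22 h against 13 h with only members above 0 in both libraries.

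With the median of ratios, genes that reversed at 22 h against 13 h were CT-43_CH0517 (1.13), glnA CT-43_CH3641 (0.87), atpC CT-43_CH5344 (0.91), pCT127.021 (0.33), pCT127.076 (0.17) and hutI CT-43_CH3594 (1.10). At 22 h against 7 h they were spoVT CT-43_CH0049 (0.22), phaP CT-43_CH1244 (0.24), phaQ CT-43_CH1245 (0.71) and hutH CT-43_CH3596 (0.37). With the sum without the 100 highest genes, they were at 22 h against 13 h CT-43_CH0049 (1.12), CT-43_CH0517 (2.51), CT-43_CH1245 (1.25), CT-43_CH3641 (2.24), rplU CT-43_CH4459 (0.43), sdhB CT-43_CH4535 (0.22), citZ CT-43_CH4614 (0.63), CT-43_CH5344 (2.28), soJ CT-43_CH5521 (0.99), pCT281.272 (0.05), pCT127.021 (1.72), pCT127.076 (1.56) and CT-43_CH3594 (2.44). At 22 h against 7 h they were CT-43_CH0049 (0.98), CT-43_CH1244 (1.01), CT-43_CH1245 (1.48), aspS CT-43_CH4419 (0.56) and CT-43_CH3596 (1.12).

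Not run were mean coverage per base in place of RPKM and coverage outside genes, since no map column could be given to a time point, and RPKM times gene length for the highest genes, since no chromosome gene lengths were used. Leaving out a library was not possible with 1 per time point. Depth limits the plasmid genes, whose median was 1, 2, 4 and 0 reads at 7, 9, 13 and 22 h, so that many of their ratios rest on few reads. The depth behind the chromosome values is unknown.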

Other observations

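The genes and groups in these first paragraphs were chosen after their values were seen, from a wider set of searches over product names. Among the tests further on, those of fewer reads and of low values listed as 0, and the spread over genes in the copy number test, were chosen after the result was seen. Genes for breathing nitrate and for using histidine had their highest values at 9 h. The nitrate reductase genes narG (CT-43_CH2067), narH (CT-43_CH2068), narJ (CT-43_CH2069) and narI (CT-43_CH2070), for respiration without oxygen, had 64.7, 57.0, 100.3 and 102 RPKM at 7 h and 249, 218, 749 and 635 at 9 h. The nitrite reductase genes nirD (CT-43_CH2083) and nirB (CT-43_CH2084) had 263 and 242 RPKM at 7 h and 638 and 444 at 9 h, and all 7 genes of the group were highest at 9 h and listed at 0 at 22 h. The histidine breakdown genes hutI (CT-43_CH3594), hutU (CT-43_CH3595) and hutH (CT-43_CH3596) had 16.3, 41.4 and 59.4 RPKM at 7 h, 499.8, 334 and 498 at 9 h, and 31.2, 89.2 and 11.2 at 13 h. tasA (CT-43_CH1209), for a biofilm fibre, had 33.4, 314, 57.9 and 0 RPKM at 7, 9, 13 and 22 h.

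Collagen-like proteins, which form hair-like layers on spores of this group, were found in the 22 h library: of 11 genes, 0, 0, 2 and 11 were above 0 at 7, 9, 13 and 22 h, and 10 were highest at 22 h. CT-43_CH2601 had 1442 RPKM and CT-43_CH3744 had 1373 there, while CT-43_CH2357 had 8806 at 13 h and 83.3 at 22 h. Cell wall amidases, which open the wall around a cell or spore, had 6, 0, 7 and 4 of their 23 genes highest at 7, 9, 13 and 22 h. CT-43_CH2234 had 11.9, 22.1, 22.7 and 7494 RPKM, CT-43_CH3622 was listed at 0 until 22 h (1652), and CT-43_CH2815 had 39.2 at 13 h and 1246 at 22 h. Among general stress genes, CT-43_CH0933 had 461, 12.7 and 506 RPKM at 7, 9 and 13 h, CT-43_CH3094 had 295, 32.7 and 406, and CT-43_CH4703 had 236, 24.6 and 548, while yugI (CT-43_CH4903), with 828, 905 and 1083, had no such dip. A short gene on pCT281, pCT281.285 (bases 277613 to 277741), had 1 read at 13 h and 1570 at 22 h (ratio 271, interval 48.7 to 10730). Of the 20 highest chromosome genes, 8, 2, 2 and 10 were listed next to another of them at 7, 9, 13 and 22 h, where the highest of 1000 random sets had 4.

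Plasmid genes had a higher median log2 ratio than chromosome genes at 13 h against 9 h, 2.07 against 0.85. An even background of DNA reads over the plasmids at 13 h, as high as their median density of 7.73 reads per kb, is argued against. At that density 54.7 genes were expected to have no read and 121 had none, a ratio of 2.21. A thinner background beneath transcribed genes, or one that differed between plasmids, could give the same counts. Whether background adds to the higher median is therefore open. A higher copy number of every plasmid at 13 h cannot be told apart from differences in transcription: 6 of the 9 plasmids had a median above that of the chromosome, but the bootstrap interval over genes lay above it for 4 and below it for 1, pCT9547, which had 2 genes, and pCT8252 (7 genes, -3.32 to 3.27) and pCT8513 (10 genes, -0.40 to 3.13) reach both sides. pCT281 lay 1.41 above it (1.17 to 1.96), and of the other 2 plasmids below it pCT6880 had 6 genes and pCT83, at -0.63 (-1.51 to 0.0), an interval that reaches 0. Separate normalization of the tables was not tested, and no biological explanation was tested.

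More genes were listed at 0 at 22 h than at 7, 9 or 13 h. For the plasmid genes, fewer reads in the 22 h library as a whole are argued against. The total behind its plasmid column, 1274050, was the highest of the 4. Outside the 10 most-read plasmid genes, however, the 22 h library had the fewest reads, 3853. On the chromosome, where 4549 genes were listed at 0 at 22 h, the depth is unknown, so the total cannot decide there. A few genes taking most of the reads at 22 h cannot be told apart from a smaller set of transcripts: with the 10 most-read plasmid genes left out and 3853 reads kept per library, 325.1, 326.7, 432.7 and 246 genes had a read, and the ratio of 0.76 lies between the bounds of 0.9 and 0.75 set for the test. Low chromosome values listed as 0 may add to the zeros of the chromosome, but the test made here cannot decide it. The share of values under 10 RPKM was at most 0.36 times that on the plasmids (0.19, 0.28, 0.36 and 0.31 at 7, 9, 13 and 22 h). Plasmid values above 0 also had lower medians, 25.7, 29.6, 56.2 and 7.04 RPKM against 133, 116, 150 and 31.7 on the chromosome. Such a difference in level could lower the share without any low value set to 0. The low share holds in every library, so it also leaves the excess at 22 h open.

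Genes that share a symbol apart from a closing number, such as gap1 (435, 766, 1121 and 1358 RPKM at 7, 9, 13 and 22 h) and gap2 (CT-43_CH5167; 5593, 1626, 789 and a listed 0), often had their highest values at different times. The hypothesis that copies of a gene are used at different times, beyond what random pairs of genes show, was not borne out over these pairs. Of 386 pairs of 173 symbols, 239 differed, 61.9% against a median of 66.8% in random pairs, at percentile 3.7. The pairs are not independent, since symbols with many copies, such as oppA, gave many of them. Random pairs were made by shuffling single genes, so the percentile does not allow for this and may rest on few symbols. Reads shared between the copies could give such a low percentile, 3.7, as could common regulation of copies, which was not tested, and both statements rest on the same number.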
